A study of Homo sapiens with 2 samples.

How the data were processed

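Single cells were sorted into the wells of plates and sequenced by a plate method that tags each transcript with a cell barcode of 6 bp and a unique molecular identifier (UMI) of 10 bp, with a cDNA read of 66 bp. The cells came from H9, an established human embryonic stem cell line that carries a green fluorescent reporter at PAX7, the gene of a transcription factor that marks satellite cells, the stem cells of skeletal muscle. Per the labels' protocols, the cells were driven toward muscle with 3 µM CHIR99021 (an inhibitor of GSK3) for 4 days and 10 µM DAPT (an inhibitor of gamma-secretase and thus of Notch cleavage) for 8 days, matured for 13 days and sorted for the reporter, and injected into the irradiated and barium chloride injured tibialis anterior muscle of immunodeficient mice. Spike-in RNA of the External RNA Controls Consortium (ERCC) was present in each well.

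The authors deposited a table of whole-number UMI counts per gene and well for each of 2 experiments, beside a well annotation with the condition, library and listed UMI total of each well. The annotation deposited by the authors also gives the spike-in percent of each well, which was not used in the comparisons. Per the submitters' processing notes, reads were aligned with STAR 2.5.4b and counted with featureCounts on GRCh38, and the UMI filters are not given in the sources used here. In experiment 1, the sum of gene counts equalled the listed UMI total in 768 of 768 wells. In experiment 2, gene and spike-in counts together made up a median of 85.0% of the listed UMIs, so this table holds part of what the annotation lists. Pseudogenes took 16.1% of the counts in experiment 1 and 7.49% in experiment 2, so a gene with near-identical copies may have lost counts to them. The design text calls the pluripotent cells embryonic stem cells and the annotation uses the abbreviation ipsc, so they are named pluripotent stem cells here.

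The annotation names libraries and sequencing lanes but no animal or culture. Each condition was therefore 1 sample: counts of all its wells were summed, and no test, p-value or standard error was made from wells. Wells with at least 500 gene counts were kept. Sums were expressed as CPM (counts per 1e6 gene counts, spike-ins left out) and compared as the log2 ratio with a pseudocount of 5 CPM on both sides. Folds are ratios of CPM without the pseudocount. Intervals at 95% are exact Poisson for a sum, exact conditional binomial for a ratio and exact binomial (Clopper-Pearson) for a share of wells; each covers counting error only and says nothing of the spread between animals or cultures. Against a sum of 0, a fold written as "at least" was computed at a floor of 3 counts over the condition. It is not an interval end, and the lower end of the exact interval can be smaller. Libraries and lanes are technical, and values within them are given as such.

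Chosen before the data were examined were 5 comparisons, 21 gene lists, 9 lists of cell type markers, the size rule of 2-fold and the rule for named genes. A list's value is the median log2 ratio of its members with at least 20 counts over both conditions, with an interval from the order statistics over its genes (a spread between genes, not samples), the number of members at least 2-fold higher or lower on the log2 scale with the pseudocount, and the percentile of the median among 10000 random lists of the same size matched on mean expression in 20 bins. The lists were pluripotency, myogenic progenitor and satellite cell, satellite cell quiescence, myogenic commitment and differentiation, muscle fibre, S phase, G2 and M phase, Notch pathway, cytosolic ribosomal proteins, mitochondrially encoded, nuclear genes of oxidative phosphorylation, glycolysis, fatty acid oxidation, extracellular matrix and basement membrane, HLA class I and antigen presentation, interferon response, immediate early and dissociation, glucocorticoid response, embryonic or fetal progenitor, postnatal satellite cell, and translation and ribosome biogenesis. The cell type markers were those of pluripotent cells, neural progenitors and neurons, neural crest and Schwann cells, fibroblasts and mesenchyme, chondrocytes, endothelial cells, blood and immune cells, epithelial cells and muscle fibres. The quiescence list shares 4 collagen genes with the matrix list and 4 genes with the Notch list. The named genes of a comparison were the 8 with the highest and the 8 with the lowest log2 ratio among genes with at least 100 counts and detected in at least 10% of wells of the higher condition, up to 3 members with at least 50 counts of each list described, and PAX7, MYF5, MYOD1, MYOG and MKI67. Mitochondrially encoded and ribosomal protein genes, clone-based names and genes of the sex chromosomes that tell the sexes apart were left out of that rule. Some genes that the rule names are not reported here.

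The share of wells with at least 3 counts over the G2 and M phase list was taken after each well was thinned at random to 500 counts. RNA content was the median over wells of gene counts per spike-in count, in wells with at least 10 spike-in counts. Week 3 against week 1 was added after only 18 usable wells were seen at week 4. Mitochondrial pseudogenes of the GENCODE annotation were divided by the share of their 25-base words that occur in the human mitochondrial genome: 368 of 394 shared under 5% and are called diverged here, and 6 shared over 50% and are called near-identical. The mouse genome was not used here.

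The alternatives tried were other well and gene minimums, equal weight for each well, thinned wells, other pseudocounts, TMM, median-of-ratios and spike-in scaling, totals without mitochondrial and ribosomal genes, the deepest wells left out, and each lane or library alone or left out. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16 for TMM factors and DESeq2 1.42.0 for size factors only. As a check of the computation, the intervals were applied to simulated data drawn from the real sums, with 50 genes at each set fold. For the month in vivo, they covered the set fold of 2 in 100% and of 4 in 94% of the genes, of 0.5 in 96% and of 0.25 in 96%, and the direction was right in 100% at each of these folds. The lowest coverages over all comparisons were 88% (a fold of 0.25, myogenic against pluripotent cells) and 90% (a fold of 2, week 4). Data drawn from sums hold counting error only, which is the error that the intervals assume. High coverage was therefore built into the draws and checks the computation alone. It cannot show whether the intervals hold for the spread between wells, libraries, animals or cultures.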

Results

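Transcripts were counted in single human cells from 8 conditions in 2 experiments. Experiment 1 held pluripotent stem cells, myogenic cells derived from them in vitro, the same kind of cells after a further month in culture, and cells recovered from mouse muscle 1 month after transplantation. Experiment 2 held transplanted cells recovered at 1, 2, 3 and 4 weeks. The title of the study names the question: whether transplanted progenitors take on the quiescent state of satellite cells, the resting stem cells of muscle. In experiment 1, 714 of 768 wells were kept. The kept wells numbered 93 of pluripotent cells, 175 of myogenic cells in vitro, 178 after the further month and 268 from mice, with sums of 5338358, 5667315, 4091312 and 3613005 UMIs. In experiment 2, 379 of 455 wells were kept, with 123, 125, 113 and 18 wells and sums of 2946996, 2522110, 990413 and 199618 UMIs at weeks 1 to 4. The median well held 53833, 34754, 10705.5 and 10832.5 UMIs in the conditions of experiment 1, and 17568, 6502, 3939 and 3019 UMIs at weeks 1 to 4. No animals or cultures are named, so no value below has a replicate check, and intervals cover counting error only.

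Gene counts per spike-in count, a measure of RNA content per well, had a median of 70.3 in pluripotent wells (quartiles 49.8 and 91.3) and 30.3 in myogenic wells in vitro (4.32 and 44.4). The median was 7.96 after the further month (0.707 and 19.7) and 11.6 in transplanted wells (6.30 and 18.9). It was 10.7 and 3.45 in the 2 libraries of the further month. The transplanted wells came from 4 libraries, and 2 of these also held all the pluripotent wells.

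Derivation of myogenic cells from pluripotent cells was compared first, to see which programmes separated them. The pluripotency list was lower in all 17 measured members, by a median log2 ratio of -3.78 (interval -4.35 to -3.07). TDGF1, a co-receptor of Nodal, stood at 213 CPM in pluripotent cells and 0 in myogenic cells, at least 402-fold lower, and L1TD1, an RNA-binding protein of pluripotent cells, was 54.3-fold lower (interval 40.5 to 74.7). Genes of myogenic commitment and differentiation were higher by a median of 2.08 (1.01 to 3.31), with 15 of 19 members at least 2-fold higher and 0 lower. MYOD1, a master regulator of muscle, was 129-fold higher (35.3 to 1067, from 0.375 to 48.2 CPM), and the sarcomere genes MYLPF and TNNI1 were 54.0-fold (40.1 to 74.5) and 27.9-fold higher. MYOG, needed for terminal differentiation, was at least 39.2-fold higher, and MEF2C was 36.1-fold higher.

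Among progenitor and satellite cell genes, 9 of 18 measured members were at least 2-fold higher and 0 lower (median 1.01, 0.47 to 1.85). PAX7, the gene of the sorted reporter (chromosome 1, 18631006 to 18748866 on the plus strand of GRCh38), was 10.4-fold higher (5.99 to 19.4), from 2.62 to 27.2 CPM. The acetylcholine receptor subunit CHRNA1 was 71.9-fold higher and caveolin CAV1 4.71-fold. MYF5 (chromosome 12, 80716912 to 80719673) had 0 counts in both conditions. MYOD1 lies on chromosome 11 at 17719568 to 17722131, MYOG on chromosome 1 at 203083132 to 203086036 and MKI67 on chromosome 10 at 128096659 to 128126385.

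The most raised named genes were S100A2 (1029.9 against 0.749 CPM), TM4SF1 (256 against 0), ANKRD1 (238 against 0), TRIM55 (202 against 1.12), S100A6 (2636 against 24.4), MT2A (1467 against 40.3), LGALS1 (8425 against 234) and MYLPF. S100A6 was 108-fold higher (91.1 to 129.6). The most lowered were ESRG (0 against 392 CPM), DMKN (0.176 against 337), LINC01405 (0.882 against 284), SCGB3A2 (0.176 against 209.6), ACTA1 (1.41 against 253), LINC00678 (0 against 194), TDGF1 and L1TD1. The postnatal satellite cell list, which holds S100A6 and LGALS1, had a median of 0.90 (0.35 to 2.19), and CD44, a receptor for hyaluronan, was 11.3-fold higher. Quiescence genes went both ways, with 4 of 24 at least 2-fold higher and 8 lower (median -0.26): the cyclin kinase inhibitor CDKN1C was higher (27.0 against 2.25 CPM), while the lipoprotein genes APOE and APOC1 were 100.0-fold and 20.5-fold lower.

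The matrix list was higher by a median of 0.62 (0.26 to 1.39), with 6 of 22 members at least 2-fold higher and 2 lower, and had a median of -0.46 under spike-in scaling, where the median of all genes was -0.97. Fibronectin FN1 was 13.5-fold higher, COL6A1 4.77-fold and vimentin VIM 4.35-fold. HLA class I and antigen presentation had a median of 1.03 (0.27 to 1.71) with 5 of 10 members at least 2-fold higher, and -0.05 under spike-in scaling. B2M, the light chain of class I molecules, was 7.73-fold higher, HLA-E 5.95-fold and HLA-B 3.82-fold. The G2 and M phase list had a median of -0.32 (-0.59 to 0.05), with -0.57 in lane 1 and 0.06 in lane 2. PLK1 was 2.26-fold lower, CCNB1 2.04-fold and AURKB 2.00-fold, while MKI67, a proliferation marker, was 1.70-fold higher (1.47 to 1.97) and had a log2 ratio of -0.55 under spike-in scaling. PLK1 was lower in lane 1 and had a log2 ratio of 0.13 in lane 2. Epithelial markers were lower by a median of -1.57. Decorin DCN, a fibroblast marker, stood at 15.0 CPM in the pluripotent wells, all of them in libraries shared with transplanted wells, and at 4.23 CPM in myogenic wells in vitro.

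**Figure D1:**
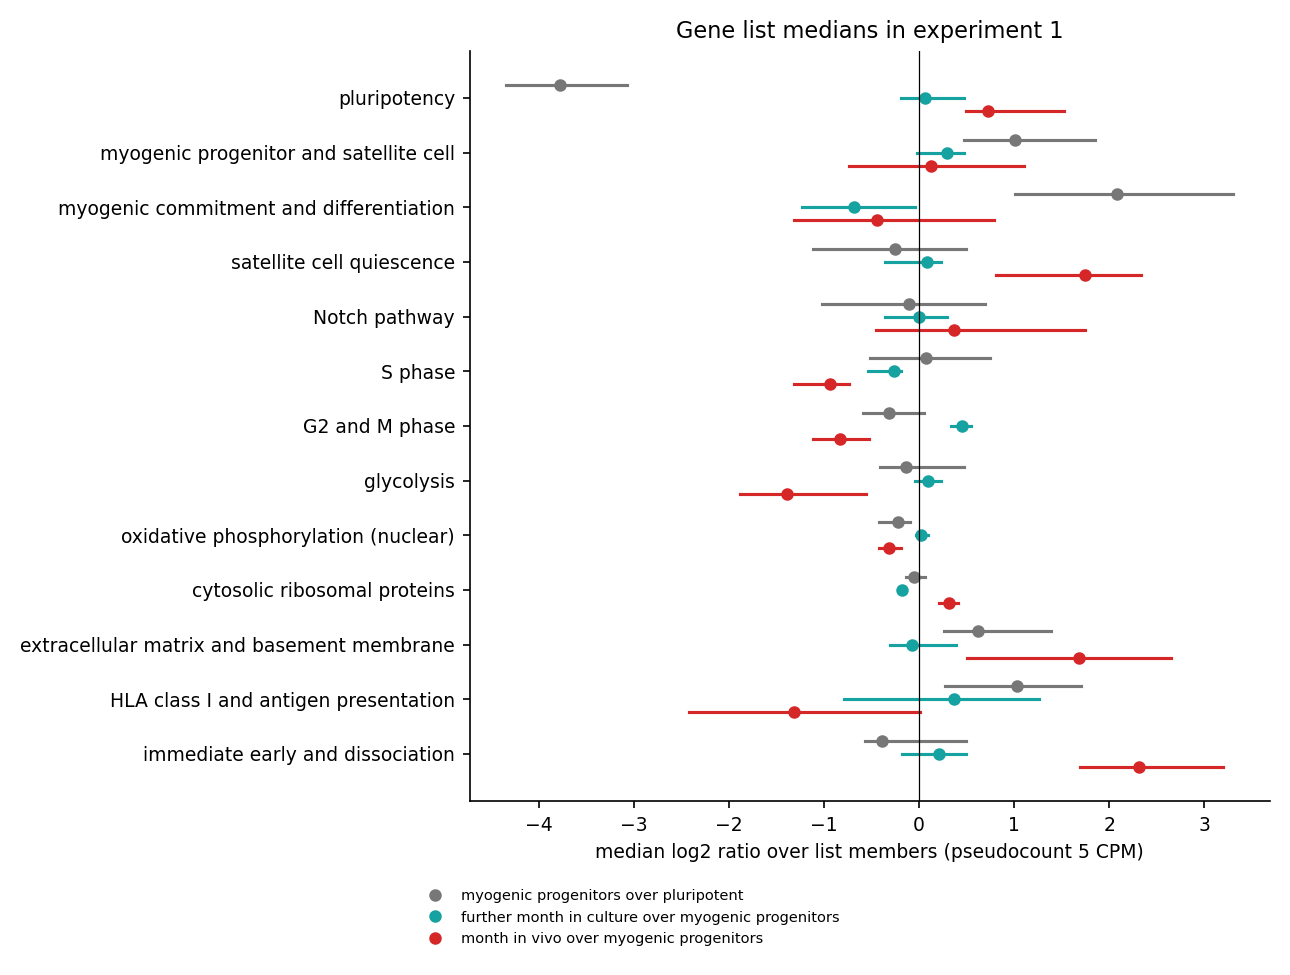
Median log2 ratio (horizontal axis) of gene lists (vertical axis) in experiment 1, for myogenic over pluripotent cells (grey), the further month in culture (teal) and the month in vivo (red), both over myogenic cells in vitro; points are medians over measured genes and lines are order-statistic 95% intervals over genes, not over samples. Pluripotency lies at -3.78 in the first comparison, and immediate early genes at 2.31 and quiescence genes at 1.75 after the month in vivo.

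Cells after the further month in culture were set against the myogenic cells in vitro. With no replicate culture and a lower RNA content per well, an effect of time alone cannot be told apart from other differences. By CPM, 116 of 15249 genes were at least 2-fold higher and 84 lower, against 1218 and 931 of 15612 after the month in vivo. With every well weighted equally, the counts were 633 higher and 554 lower, against 1970 and 1059. Under spike-in scaling, with all-gene medians of -0.82 and -0.75, the counts were 5 higher and 5342 lower, against 306 and 5635. The commitment and differentiation list was lower by a median of -0.69 (-1.23 to -0.05), with 8 of 19 members at least 2-fold lower and 0 higher. MYLPF was 21.7-fold lower (17.4 to 27.3), troponin TNNC1 11.6-fold, MYOG 3.11-fold (2.06 to 4.84) and TTN, the gene of titin, 4.03-fold. TTN had log2 ratios of 0.43 in lane 1 alone and 0.32 without the second library of the myogenic cells in vitro. The myosin light chain gene MYL1 was 18.3-fold lower.

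Progenitor genes had a median of 0.30 (-0.03 to 0.47) and 1 of 19 members at least 2-fold higher. PAX7 was 1.46-fold higher (1.16 to 1.83) and MYOD1 1.34-fold (1.13 to 1.59), CHRNA1 2.11-fold, RAPSN 1.93-fold and CDH15 1.71-fold, and each of these 5 genes had a negative log2 ratio under spike-in scaling, where the median of all genes was -0.82. MYF5 again had 0 counts. The S phase list was lower by a median of -0.26 (-0.54 to -0.19), with 19 of 22 members lower and 3 higher, -0.39 in lane 1 and -0.15 in lane 2. The G2 and M phase list had a median of 0.45 (0.33 to 0.55), but -0.74 under spike-in scaling, 0.82 in lane 1 and -0.09 in lane 2. PLK1 was 2.88-fold higher, and HMMR (1.86-fold) and KIF23 (1.81-fold) were higher, with negative log2 ratios under that scaling; MKI67 differed by 1.03-fold (0.894 to 1.18). The named genes that were higher included SCG2 (17.1-fold), ZFP42 (24.1-fold), NNMT (12.8-fold), SERPINB7 (5.80-fold), SLC7A8 (6.55-fold), MANEA (6.38-fold) and RRBP1 (3.46-fold). CD74, the invariant chain of class II molecules, was 14.4-fold lower, CDKN1C 10.0-fold, and the histone genes HIST1H2AE, HIST1H2AI and HIST1H2AJ 5.14-fold, 4.23-fold and 4.42-fold. In the HLA list, 2 of 10 members were at least 2-fold higher, HLA-C by 3.03-fold and HLA-B by 2.49-fold, and 1 was lower. In the postnatal list (median 0.30, -0.94 under spike-in scaling), CD44 was 2.06-fold higher, ANXA1 1.97-fold and ANXA2 1.67-fold, and all 3 genes had negative log2 ratios under spike-in scaling (-0.22 for CD44, against -0.82 for all genes).

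Cells after 1 month in mouse muscle were compared with the cells in vitro to ask whether they had moved towards quiescence. Quiescence genes were higher by a median of 1.75 (0.81 to 2.33), with 17 of 24 at least 2-fold higher and 2 lower, above all 10000 random lists. Of these genes, 4 are collagens of the matrix list, and the medians of fibroblast markers (4.91) and immediate early genes (2.31) were higher in the same wells. The medians were 1.46 in lane 1 and 1.66 in lane 2. DLK1, a Notch ligand-like protein of fetal and resting progenitors, went from 0 to 659 CPM, at least 1245-fold higher at the floor (exact interval from 1012-fold). APOC1 was 18.5-fold higher (13.4 to 26.1) and the collagen gene COL5A1 stood at 200.4 against 18.2 CPM. The Notch list had 4 of 10 members at least 2-fold higher and 0 lower (median 0.37, and -0.48 under spike-in scaling, where the median of all genes was -0.75), among them the receptor NOTCH3 (6.14-fold), its target HEYL (6.85-fold) and the ligand JAG1 (4.76-fold).

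Cell cycle genes were lower: the S phase list by a median of -0.94 (-1.31 to -0.74) with 9 of 22 members at least 2-fold lower, and the G2 and M phase list by -0.83 (-1.12 to -0.53) with 9 of 24, and 0 higher in either list, both below all 10000 random lists. In lanes 1 and 2 the G2 and M phase medians were -0.62 and -0.99. ANLN, a protein of the cleavage furrow, was 4.31-fold lower (3.15 to 6.01), cyclin CCNA2 3.43-fold and BIRC5 2.93-fold. SLBP, which binds histone mRNA, was 3.62-fold lower, the ribonucleotide reductase subunit RRM2 3.13-fold and CLSPN 3.12-fold, and MKI67 was 1.23-fold lower (1.06 to 1.43). SLBP had a log2 ratio of 1.04 when each well was thinned to 500 counts.

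After thinning, 9 of 268 transplanted wells held at least 3 G2 and M phase counts (3.36%, 1.55 to 6.28). The share was 17 of 175 in myogenic wells in vitro (9.71%, 5.76 to 15.1), 31 of 178 after the further month (17.4%, 12.2 to 23.8; 23 of 90 wells, 25.6%, in library 1 and 8 of 88, 9.09%, in library 2) and 15 of 93 in pluripotent wells (16.1%, 9.32 to 25.2). The unthinned shares, at the median depths given above, were 74.6%, 91.4%, 71.9% and 98.9% in the same order.

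**Figure D2:**
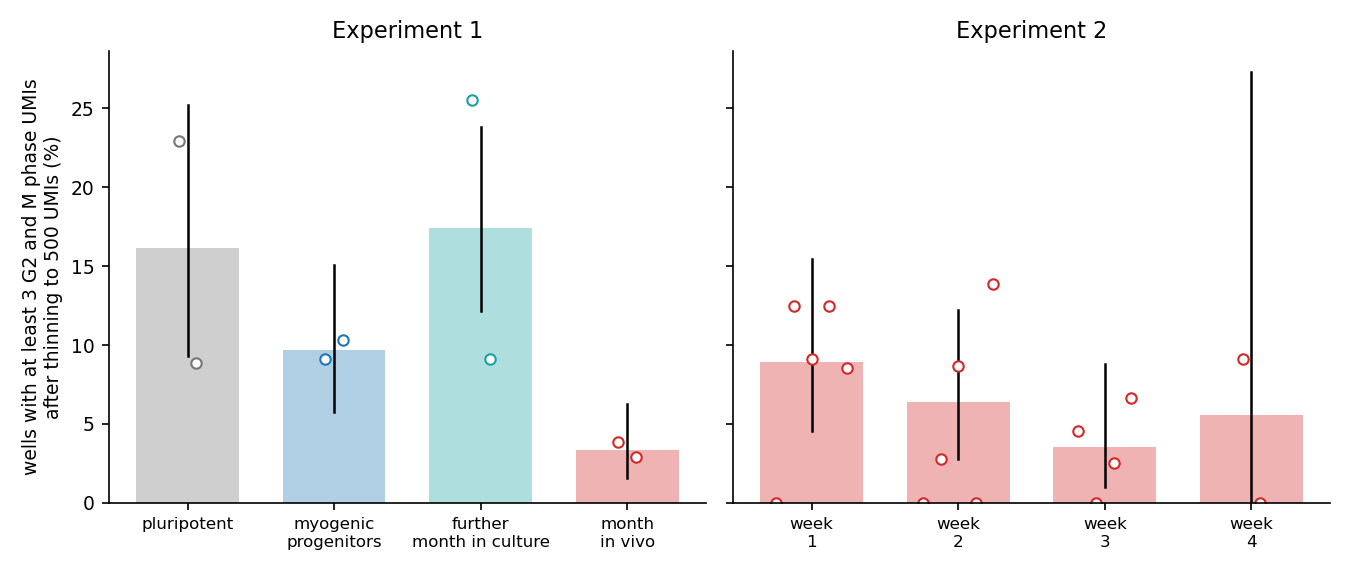
Percent of wells with at least 3 counts over the G2 and M phase list after thinning to 500 counts (vertical axis) in each condition; bars are shares, lines exact binomial 95% intervals and open circles single lanes or libraries. The transplanted wells at 1 month lie at 3.36%, against 9.71% in myogenic wells in vitro and 17.4% after the further month in culture (25.6% and 9.09% in its libraries).

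Progenitor genes had a median of 0.13 (-0.74 to 1.11), with 7 of 21 at least 2-fold higher and 4 lower. PAX7 was 1.45-fold higher (1.14 to 1.83) by CPM and had a log2 ratio of -0.65 under spike-in scaling. MEOX2, a homeobox factor of limb muscle, was 51.4-fold higher, whereas CAV1 was 9.42-fold lower. MYOD1 was 2.85-fold lower (2.15 to 3.83) and MYOG differed by 1.19-fold (0.877 to 1.63). MYF5 stood at 2.49 CPM against 0, at least 4.71-fold higher, with a count in 5 of 268 wells. The commitment list had 8 of 22 members at least 2-fold lower and 3 higher (median -0.44, with -1.15 in lane 1 and -0.03 in lane 2), and TNNI1 was 13.1-fold lower, MEF2C 11.8-fold and TNNT2 9.13-fold. Genes of mature fibres were at least 2-fold higher in 5 of 9 members (median 1.61, with 0.50 in lane 1, 2.19 in lane 2 and 0.52 without the 50% of wells richest in diverged pseudogenes): ACTA1, skeletal actin, was 36.5-fold higher, and the adult myosins MYH1 and MYH2 at least 50.2-fold and 30.8-fold, against 0 counts in vitro.

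Matrix and basement membrane genes were at least 2-fold higher in 14 of 22 members and lower in 0 (median 1.68, 0.50 to 2.65). COL3A1 was 59.6-fold higher (52.7 to 67.7, at 2724 CPM), COL1A1 22.4-fold (21.1 to 23.7) and DCN, a collagen-binding proteoglycan, 269.7-fold (181 to 421, at 1142 CPM). Most markers of fibroblasts and mesenchyme were higher in the same wells, with a median of 4.91 (-0.78 to 6.96, an interval that spans 0). Of 8 members, 6 were at least 2-fold higher and 2 were lower (medians of 5.04 and 4.77 in the lanes). Of the 10 listed markers, 3 are also in the matrix list. DCN, COL1A1 and COL3A1 were the shared members. The other genes with the highest ratios were MGP (248-fold), an inhibitor of calcification, the proteoglycans LUM (334-fold) and OGN (at least 869.5-fold), the membrane protein ITM2A (431-fold) and SPARCL1 (226-fold). The imprinted genes IGF2 and H19, in the embryonic or fetal list (median -0.10), were 14.0-fold and 8.45-fold higher, and HMGA1 was 11.6-fold lower.

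Glycolysis genes were lower in the transplanted wells, by a median of -1.39 (-1.89 to -0.56), with 10 of 17 at least 2-fold lower and 1 higher. Pyruvate kinase PKM was 7.32-fold lower (6.67 to 8.04), LDHA 6.60-fold (6.12 to 7.13) and GAPDH 5.66-fold (5.34 to 5.99). Nuclear genes of oxidative phosphorylation had a median of -0.31 (-0.42 to -0.19), mitochondrially encoded genes 0.01 and fatty acid oxidation -0.07. Antigen presentation was lower by a median of -1.32 (-2.42 to 0.01), with 7 of 10 members at least 2-fold lower and 0 higher. HLA-C was 9.70-fold lower (6.03 to 16.6) and CD74 21.3-fold. The lowest ratios among named genes were those of S100A2 (169-fold), the metallothionein MT2A (76.8-fold, 60.6 to 98.8), ANKRD1 (71.7-fold), the urokinase gene PLAU (67.4-fold), NQO1 (36.2-fold), TM4SF1 (35.6-fold) and MT1E (29.9-fold). MT2P1, 32.8-fold lower, is a pseudogene that can take counts from MT2A, so its own value is uncertain.

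Immediate early and dissociation genes, which respond within minutes to tissue handling, were at least 2-fold higher in the same wells in 14 of 17 members (median 2.31, 1.70 to 3.20). FOS was 171-fold higher (92.5 to 357), FOSB at least 274-fold, and ZFP36 274-fold (75.2 to 2269). Ribosomal protein genes had a median of 0.32, and -0.96 under spike-in scaling. The remaining lists had medians of 0.40 for interferon response (-0.28 under spike-in scaling), 0.39 for glucocorticoid response (-0.62), 0.28 for the postnatal satellite cell list (-0.97) and -0.12 for translation and ribosome biogenesis. Among other cell type markers, medians were 0.59 for neural, 0.03 for endothelial, 0.34 for blood and immune, -0.12 for epithelial, -0.63 for chondrocyte and 1.94 for muscle fibre markers, and 1 measured neural crest gene had 2.66.

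The pluripotency list had a median of 0.72 (0.49 to 1.53) and the pluripotent cell markers 1.14. In the 177 transplanted wells of libraries without pluripotent wells the pluripotency median was 0.12 (-0.09 to 0.29), and in the 91 wells of the libraries shared with them it was 2.01 (0.75 to 3.31). Diverged mitochondrial pseudogenes, which share few words with the human mitochondrial genome, stood at 1250.5 CPM in transplanted wells and 32.3 CPM in myogenic wells in vitro.

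**Figure D3:**
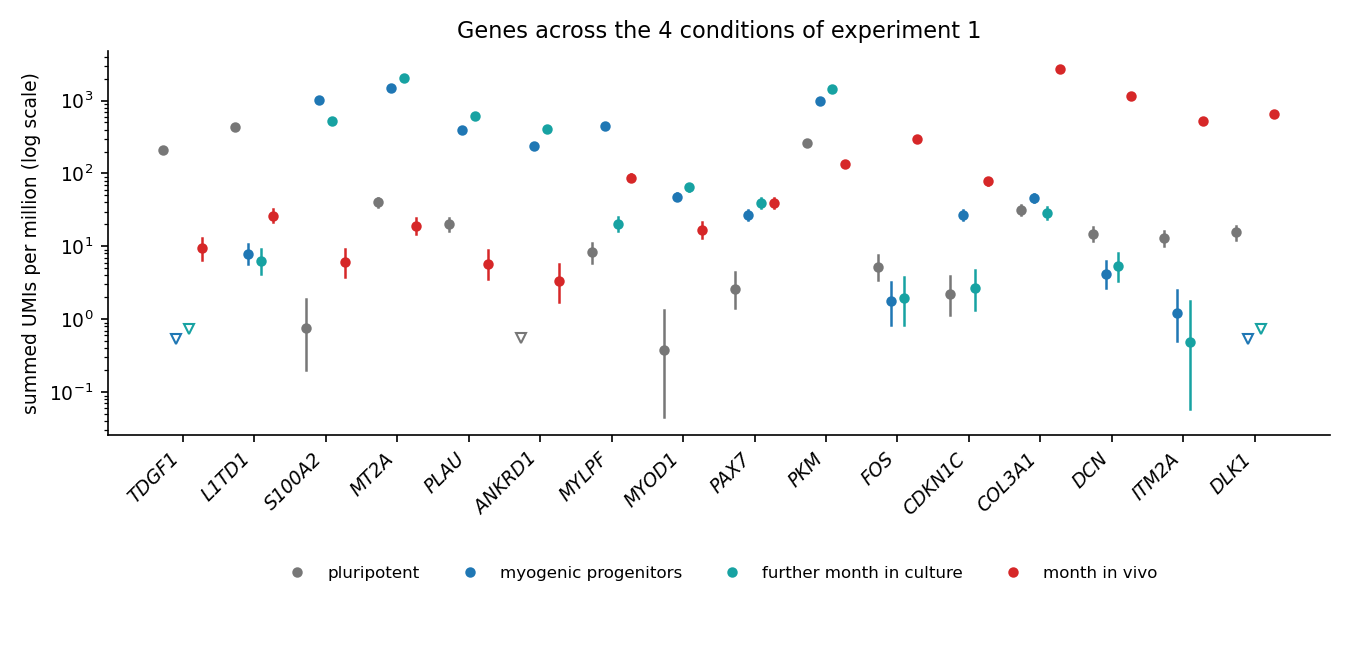
CPM (log axis) of 16 genes named in the text in each condition of experiment 1, with exact Poisson 95% intervals of the summed counts; open triangles mark the floor of 3 counts where the sum was 0. DCN lies at 1142 CPM and COL3A1 at 2724 CPM in transplanted wells, where PLAU lies at 5.81 CPM and MT2A at 19.1 CPM.

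Transplanted cells were also set against cells that spent the further month in culture. Quiescence genes were higher by a median of 1.96 (0.95 to 2.68), with 17 of 25 at least 2-fold higher and 2 lower, and CDKN1C was 28.9-fold higher (15.9 to 58.6) and APOC1 34.3-fold. The G2 and M phase list was lower by -1.29 (-1.50 to -0.93), with 16 of 24 at least 2-fold lower, -1.51 in lane 1 and -0.91 in lane 2. PLK1 was 8.64-fold lower (5.85 to 13.2), ANLN 6.45-fold and CCNB1 3.90-fold, and the S phase median was -0.60. Without the first library of the further month the G2 and M phase median was -0.75. PAX7 differed by 1.01-fold (0.799 to 1.27), MKI67 was 1.20-fold lower (1.02 to 1.41), MYOD1 3.82-fold lower (2.88 to 5.14) and MYOG 2.62-fold higher (1.67 to 4.20), while MYF5 was at least 3.40-fold higher. The progenitor list had a median of -0.01.

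Matrix genes were at least 2-fold higher in 12 of 22 members (median 1.35, 0.65 to 2.84), with COL3A1 93.6-fold (78.2 to 113) and DCN 212-fold higher, beside a fibroblast marker median of 4.87 (-0.46 to 6.79) and an immediate early median of 2.09. DLK1 was at least 899-fold higher at the floor (exact interval from 731-fold), and POSTN (416-fold, 142 to 2022), PLAC9 (273-fold), SPARCL1 (254-fold), ITM2A (532 against 0.489 CPM) and OGN (460.3 against 0.244 CPM) were higher too. Glycolysis was lower by -1.54 (-2.23 to -0.41), with PKM 10.7-fold, PFKP 10.0-fold and LDHA 6.09-fold lower. In antigen presentation (median -1.88, -2.81 to -0.21), 5 of 9 members were at least 2-fold lower and 0 higher, with HLA-C 29.4-fold and HLA-B 8.07-fold. MT2A was 107-fold lower, PLAU 106-fold, ANKRD1 121-fold, S100A2 85.7-fold, the growth factor PGF 65.4-fold and TM4SF1 41.1-fold, beside the metallothionein pseudogenes MT2P1 (47.7-fold) and MT1XP1 (79.3-fold), whose counts can come from the parent genes.

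Experiment 2 followed the transplanted cells by week. The G2 and M phase list was lower at week 4 than at week 1 by a median of -1.39 (-1.81 to -0.85), with 15 of 23 members at least 2-fold lower and 0 higher. The S phase list was lower by -1.33 (-2.27 to -0.25). MKI67 stood at 136, 110, 84.8 and 20.0 CPM at weeks 1 to 4, 6.77-fold lower at week 4 (Poisson interval 5.46 to 51.3 CPM) than at week 1 (122.8 to 149.7 CPM). CDK1 was 24.9-fold lower (4.45 to 987), ANLN 13.6-fold (2.42 to 540.4) and NDC80 at least 5.04-fold, but CDK1 had a log2 ratio of 1.11 with wells thinned to 500 counts. Week 4 rests on 18 wells of 2 libraries, and the median of all measured genes was -0.37. Deep wells weigh most in the sums: the deepest well, in library 1, held 72192 of the 199618 UMIs at week 4, while the median well held 3019. All week 4 CPM and folds therefore lean on few wells. With every well weighted equally, the median of all genes was -0.82. Library 1 alone gave a G2 and M phase median of -0.75, and spike-in scaling -0.29, where the median of all genes was 0.63. Gene counts per spike-in count had medians of 97.0 at week 1 and 70.9 at week 4 in library 1, against 18.1 and 12.8 in library 2. Library 1 gave 168704 of 199618 UMIs at week 4 and 262423 of 2946996 at week 1. Values under spike-in scaling at week 4 therefore mix library make-up with RNA content.

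PAX7 stood at 69.6, 148, 64.6 and 215 CPM and was 3.10-fold higher at week 4 than at week 1 (2.18 to 4.32), with a log2 ratio of -0.01 in library 2 alone. MYOG stood at 71.9, 36.1, 100.0 and 5.01 CPM, 14.4-fold lower at week 4 (2.55 to 569.8), and MYOD1 at 47.5, 37.7, 41.4 and 30.1 CPM, a difference of 1.58-fold (0.708 to 4.38). MYF5 was absent from the genes counted in experiment 2, so it has no value there. The progenitor list had a median of -0.16 (1.03 under spike-in scaling). Quiescence genes went both ways, with 5 of 21 at least 2-fold higher and 8 lower (median -0.49, 0.58 under spike-in scaling): DLK1 was 9.42-fold higher (7.77 to 11.4), APOE 5.81-fold lower and the Notch target HEY1 at least 5.35-fold lower. Of all 12952 measured genes, 2099 were at least 2-fold higher and 4267 lower at week 4, with no minimum of counts per well. The quiescence counts lie near these shares, and no change of the list is read from them. The matrix list had a median of -0.27 (0.97 under spike-in scaling), and COL1A1 stood at 3124, 3675, 3064 and 5079.7 CPM and DCN at 1203, 1133, 1095.5 and 1132 CPM in weeks 1 to 4. After the month in vivo of experiment 1, COL1A1 (4815 CPM) and DCN (1142 CPM) were close to week 4. PAX7 (39.3 CPM) was lower there and MKI67 (73.9 CPM) higher than at week 4 of experiment 2. The levels at 1 month thus differed between the experiments for some genes.

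The genes with the highest ratios at week 4 were SLC1A3 (61.0-fold), CAPN6 (63.3-fold), COLEC12 (44.6-fold), ATP11A (26.7-fold), SOCS3 (24.9-fold), DLC1 (20.3-fold), PLPP1 (17.9-fold) and the matrix protein gene POSTN (2249 against 133 CPM). Without library 1, the log2 ratios were -1.40 for SLC1A3, -1.23 for COLEC12, -1.99 for ATP11A and -0.63 for DLC1, where the median of all genes was -1.40. TCEAL8, ID1 and VCAM1 had 0 counts at week 4, at least 12.9-fold, 10.8-fold and 10.4-fold lower, as had PAICS, PDCD5, GTF2A2 and NHP2, and PEG10 was 52.9-fold lower (9.47 to 2092). Ribosomal protein genes were at least 2-fold lower in 48 of 82 members (median -1.14, 0.09 under spike-in scaling), oxidative phosphorylation in 54 of 83 (-1.31) and glycolysis in 8 of 17 (-0.83, 0.41 under spike-in scaling). These counts stand beside 4267 of all 12952 genes that were at least 2-fold lower, with no minimum of counts per well. Immediate early genes had a median of 1.00 and diverged pseudogenes 16206.0 CPM at week 4 (18547 in library 1 and 3429 in library 2) against 2192 CPM at week 1 (3952 in library 1 and 3479 in library 2). Within library 2 they were thus not higher at week 4.

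Week 3 against week 1, added after the number of wells at week 4 was seen, compared 113 with 123 wells. With no minimum of counts per well, 1492 of 13857 genes were at least 2-fold higher and 1844 lower. The G2 and M phase list was lower by -0.65 (-1.07 to -0.50), with 9 of 24 members at least 2-fold lower and 0 higher, and medians of -0.01, -0.99, -0.05 and -1.0 in the libraries 1 to 4. KIF20A was 13.7-fold lower (6.21 to 37.8), DLGAP5 12.9-fold, NDC80 6.81-fold, CCNB2 6.39-fold and CDK1 4.12-fold, and MKI67 was 1.60-fold lower (1.26 to 2.05). In library 3 alone, the log2 ratios of CCNB2 and CDK1 were 0.40 and 1.64. NDC80 had 2.18 with wells thinned to 500 counts.

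PAX7 differed by 1.08-fold (0.809 to 1.45), MYOD1 by 1.15-fold (0.805 to 1.67), and MYOG was 1.39-fold higher (1.08 to 1.77, with a log2 ratio of -0.08 under spike-in scaling, where the median of all genes was -0.59). The progenitor list had a median of 0.15 and the matrix list -0.06. Muscle fibre genes were at least 2-fold higher in 5 of 7 members (median 1.37, and 1.04, -0.02, 0.40 and 3.29 in libraries 1 to 4), with ACTA1 8.39-fold, TNNT3 7.50-fold and MYL1 3.03-fold. Without library 4, the log2 ratios of TNNT3 and MYL1 were -0.35 and -1.04. The chaperone of myosin UNC45B was 19.7-fold higher, tenomodulin TNMD 25.8-fold, the microfibril gene MFAP5 13.9-fold, SFRP4 9.29-fold and REXO4 8.39-fold, and ITM2A stood at 179 against 14.9 CPM, beside the mitochondrial pseudogenes MTATP6P9 (442 CPM at week 3) and MTCO3P38 (9.25-fold). MEPCE was at least 12.9-fold lower, and GFM1 (1.01 against 46.1 CPM), PHLDA2 (1.01 against 44.1), POLR3K (3.03 against 60.1), TUBGCP6 (2.02 against 47.8) and BRMS1 (2.02 against 46.5) were lower. Among fetal genes, HMGA2 was 2.59-fold lower, HMGA1 2.86-fold and H19 2.42-fold (2.28 to 2.56). Oxidative phosphorylation had a median of -0.45 (0.27 in library 4 alone), glycolysis -0.65 (0.31 in library 1 alone) and ribosomal protein genes -0.33 (0.09 in library 2 alone).

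The share of wells with at least 3 G2 and M phase counts after thinning was 11 of 123 (8.94%, 4.55 to 15.4), 8 of 125 (6.40%, 2.80 to 12.2), 4 of 113 (3.54%, 0.973 to 8.82) and 1 of 18 (5.56%, 0.141 to 27.3) at weeks 1 to 4. The shares were 82.9%, 63.2%, 53.1% and 50.0% before thinning. Unthinned, a PAX7 count was found in 12.9% of pluripotent, 37.7% of myogenic, 29.8% of further-month and 23.5% of transplanted wells, and in 42.3%, 44.0%, 26.5% and 44.4% of wells at weeks 1 to 4. Unthinned shares, at the unequal median depths given above and thus not compared between conditions, were 2.15%, 53.7%, 44.9% and 11.9% for MYOD1 in experiment 1. For MYOG they were 0 of 93 wells (where 3 wells would make 3.23%, a floor and not an interval end), 20.6%, 5.62% and 9.33% (3 of 130 wells in lane 1 and 22 of 138 in lane 2), and for MKI67 64.5%, 54.3%, 37.1% and 25.4%. Thinned to 500 counts, the PAX7 share was 0 of 93, 1.14%, 1.69% and 4.10% in experiment 1; these levels rest on about 1 count per well, and no order is read from them.

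**Figure D4:**
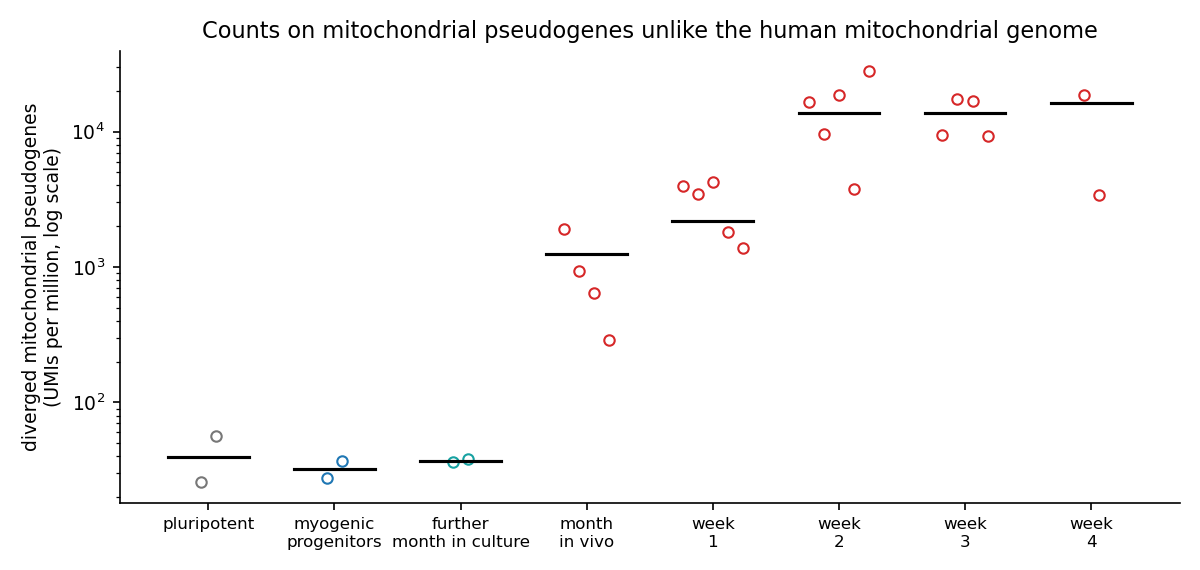
CPM (log axis) of diverged mitochondrial pseudogenes in each condition of both experiments; short lines are sums over a condition and circles single libraries. The conditions that were never in mice lie at 39.7 CPM or below, and the transplanted conditions between 1250.5 and 16206.0 CPM.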

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

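Of the tests below, only the one of mouse RNA as a source of the fibroblast markers was set out before its result was seen; the others were chosen after it.

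The medians of some gene groups differed between the further month in culture and the month in mice, against the same myogenic cells in vitro. Antigen presentation had a median log2 ratio of 0.37 after the further month in culture (-0.79 to 1.26, with 6 members higher and 4 lower) and -1.32 after the month in vivo (-1.24 and -1.69). Glycolysis had 0.09 (-0.05 to 0.23) and -1.39 (-1.28 and -1.35). Ribosomal protein genes had -0.18 (-0.18 and -0.21) and 0.32 (0.33 and 0.27), and nuclear oxidative phosphorylation genes 0.02 (-0.03 to 0.09) and -0.31. The lanes are technical, both contrasts share 1 control, and the differences were not tested. Under spike-in scaling, which shifted the median of all genes by -0.88 and -0.86, antigen presentation had -0.83 after the further month and -2.48 in vivo, and glycolysis -1.12 and -2.56.

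Fibroblast and mesenchyme markers had a median of 4.91 (-0.78 to 6.96, with 6 of 8 higher and 2 lower) in the transplanted wells, although the cells were sorted on a PAX7 reporter. Mouse RNA read as human was tested in the 67 transplanted wells with the smallest share of diverged pseudogene counts, where these counts were 59.8 CPM against 4958 CPM in the 67 wells with the largest. The marker median there was still 4.45, and DCN stood at 991 CPM against 1137 CPM. That argues only against mouse RNA that goes with these counts as the whole cause. The source of these counts stays open (below), so mouse RNA that does not go with them was not tested. A separate cell type sorted beside the PAX7 cells was tested in wells with a PAX7 count by DCN above 3 UMIs. That is the 95th percentile of pluripotent wells, where 9 of 12 PAX7 wells held some DCN (at 14.5 CPM). Of the transplanted wells, 53 of 63 lay above it (84.1%, 72.7 to 92.1, with 3 of 7 in the second shared library), as did 24 of 28 with at least 2 PAX7 UMIs. Some DCN was nearly as common in transplanted wells without a PAX7 count (189 of 205, 92.2%) as in those with one (61 of 63, 96.8%). A PAX7 count occurred in pluripotent wells too, and the cut of 3 UMIs came from the shared libraries only. The test therefore cannot decide on a separate type, which stays open. Carry-over among transplanted wells could add to these shares and stays open, as do doublets. A change of the human cells towards matrix production in muscle remains a hypothesis that no replicate animal tests here.

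Pluripotency transcripts were higher in the transplanted wells (median 0.72). Carry-over from pluripotent wells was tested by library: in the transplanted wells of libraries without pluripotent wells the median was 0.12, and in those of the shared libraries 2.01, which is in line with carry-over of barcodes or RNA. A few pluripotent cells among the transplanted wells would raise few wells, but 89.0% of the 91 wells in shared libraries lay above the upper quartile of the others. TDGF1 had 19 and 15 UMIs in the shared libraries and 0 in each of the others, and 6 and 4 wells in the shared libraries reached the 5th percentile of pluripotent wells, so single pluripotent cells among these stay open. In the other direction, 50.5% of pluripotent wells held DCN, against 9.71% of myogenic wells in vitro.

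Diverged mitochondrial pseudogenes, which no gene list held, stood above the level of all conditions never in mice: 1250.5 CPM after the month in vivo, and 2192, 13658, 13608.5 and 16206.0 CPM at weeks 1 to 4. After the month in vivo their median log2 ratio was 2.76, with 23 of 23 measured members higher, and near-identical human pseudogenes had -0.37. More human mitochondrial RNA is argued against by the mitochondrially encoded genes, whose median was 0.0063. RNA from mouse host cells was tested by muscle fibre genes, which host muscle would bring: in the 67 wells with the largest diverged share over the 67 with the smallest, their median was 1.79 (0.74 to 3.34), but 0.39 in lane 1 and 3.02 in lane 2. Mouse and human fibre RNA cannot be told apart here, since the mouse genome was not used, so the source of these counts stays open and no biological explanation was tested.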

How the results depend on the processing

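The week 3 comparison and the omissions of transplanted wells were chosen after the data were seen. For the lists that answer the 5 planned comparisons, 289 of 315 alternative values stayed within their interval, 22 moved out of it and 4 reversed (matrix in myogenic against pluripotent cells and G2 and M phase in the further month under spike-in scaling, with all-gene medians of -0.97 and -0.82 there, and G2 and M phase in the further month in lane 2 and without its first library); for the other lists 2492 of 2698 stayed, 195 moved and 11 reversed, and for named genes 2291 of 4036 stayed, 1718 moved and 27 reversed. A sign change counts as reversed only where the reported interval excludes 0 and, for a gene, the change is at least 2-fold; in all, 28, 246 and 79 of these values changed sign, most of them within the interval for lists. Shares and RNA contents, which have no sign, stayed in 26 of 76 and moved in 50. No paired analysis was possible because no animals or cultures are named; for the same reason the alternatives that need a test were not run, and thinning to 500 counts was already the depth used for shares. Causes below were not tested unless stated.

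Spike-in scaling multiplies all CPM of a condition by 1 factor, but the pseudocount of 5 CPM makes the log2 shift smaller for genes with few counts. The median of all genes moved by -0.87 (myogenic against pluripotent cells), -0.88 (further month), -0.86 (month in vivo), 1.00 (week 4) and -0.45 (week 3). At week 4 the factor also mixes libraries of unlike spike-in ratio. In the month in vivo, ribosomal protein genes went from 0.32 to -0.96, while the median of all genes went from 0.11 to -0.75. A direction relative to the median of all genes can therefore change with expression level alone. The largest other shifts of that median were at week 4: -1.72 with thinned wells, -1.03 without library 1, -0.45 with equal weight, 0.37 in library 1 alone and -0.36 in library 2 alone. They were 0.24 with equal weight for transplanted wells against the further month and -0.28 in library 4 alone at week 3; the rest lay between -0.15 and 0.20. Under spike-in scaling, myogenic against pluripotent cells had 0.081 for the progenitor list, -1.56 for G2 and M phase, -0.46 for matrix and -0.049 for antigen presentation. The further month had -0.63 for progenitor, -0.74 for G2 and M phase, -1.0 for matrix and -0.32 for neural markers, -0.19 for CHRNA1 and -0.22 for CD44. The month in vivo had -1.93 for G2 and M phase and -0.96 for ribosomal proteins. Week 4 had 1.03 for progenitor, -0.29 for G2 and M phase, 0.094 for ribosomal proteins, 0.41 for glycolysis and 0.97 for matrix.

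With wells thinned to 500 counts, the matrix median of myogenic against pluripotent cells was 1.59, the G2 and M phase median 0.28 for the further month and -2.09 for week 4, where the median of all genes was also -2.09, and log2 ratios were 0.47 for TTN (further month), 1.04 for SLBP (month in vivo), 1.11 for CDK1 (week 4) and 2.18 for NDC80 (week 3); few counts are left at that depth.

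In experiment 1, lane 2 alone gave 0.063 for G2 and M phase and 0.13 for PLK1 in myogenic against pluripotent cells. For the further month, G2 and M phase was 0.82 in lane 1, -0.093 in lane 2, -0.0075 and 0.81 without the first and second library of that month and 0.67 without the deepest 5% of wells, and TTN was 0.43 in lane 1 and 0.32 without the second library of the cells in vitro. Transplanted wells against the further month had a G2 and M phase median of -1.51 in lane 1, -0.91 in lane 2, and -0.75 and -1.65 without the first and second library of the further month.

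At week 4, G2 and M phase was -0.75 in library 1 alone, -2.54 without library 1 and -1.91 without the 50% of wells richest in diverged pseudogenes. COLEC12 and ATP11A were both -0.86 and PAX7 -0.0084 in library 2 alone. Without library 1, SLC1A3 was -1.40, COLEC12 -1.23, ATP11A -1.99, DLC1 -0.63 and PAX7 -0.063, against -1.40 for the median of all genes; that leaves 7 wells at week 4.

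At week 3, library 1 alone gave 0.31 for glycolysis, -0.67 for TNNT3 and 0.23 for NDC80. Library 2 alone gave -0.019 for muscle fibre, 0.094 for ribosomal proteins, -3.31 for TNNT3 and -3.06 for MYL1. Library 3 alone gave -0.45 for MYL1, 0.40 for CCNB2 and 1.64 for CDK1, and library 4 alone 0.19 for ribosomal proteins and 0.27 for oxidative phosphorylation. Without library 4, TNNT3 was -0.35 and MYL1 -1.04; without library 5, ribosomal proteins were 0.051. MYL1 was -0.92 without the 50% of wells richest in diverged pseudogenes. Week 4, with 199618 UMIs, limits what can be read of single genes there.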

Other observations

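The lists below were chosen after the data were seen, from genes already named above that are among their members, and no test was run on them.

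Imprinted genes with roles in fetal growth were at least 2-fold higher after the month in vivo in 6 of 11 measured members and lower in 0 (median log2 ratio 1.37, 0.12 to 3.76, with 1.06 and 1.84 in the lanes). DLK1, IGF2, H19 and CDKN1C, which prompted the list, are 4 of these 6; without the genes named above, 2 of 6 members were at least 2-fold higher and the median was 0.72 (-0.89 to 2.81). PLAGL1, a zinc finger factor that regulates other imprinted genes, was 9.71-fold higher and MEST 4.61-fold. After the further month in culture the same list had a median of -0.18 (-0.94 to 0.21). In experiment 2, IGF2 stood at 8256, 10341 and 7211 CPM in weeks 1 to 3 and 15675 CPM at week 4, and H19 at 3333, 2296, 1378 and 3171 CPM, but the list had 1 member at least 2-fold higher and 3 lower at week 4 against week 1 (median 0.23, -2.09 to 0.98) and 2 higher and 2 lower at week 3. After the month in vivo of experiment 1, IGF2 stood at 1914 CPM and H19 at 547 CPM, far below week 4 of experiment 2. The cause of this gap was not tested.

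Lists of stress and mechanical response genes had lower medians after the month in vivo. Metallothioneins were at least 2-fold lower in 5 of 7 members and higher in 0 (median -2.53, -5.93 to -0.31), of which MT2A and MT1E were named above and the other 5 measured members had a median of -2.02. Targets of NRF2, the regulator of the antioxidant response, were at least 2-fold lower in 5 of 15 (median -0.74, -1.08 to -0.25), with NQO1 among them. Targets of YAP and TEAD, which respond to stiffness and spreading, were at least 2-fold lower in 4 of 11 (median -0.88, -3.15 to -0.12): besides ANKRD1, NT5E was 24.7-fold lower, CRIM1 9.07-fold and AXL 5.13-fold, while CTGF was 1.68-fold higher (1.31 to 2.15). Against the further month, 5 of these 11 were at least 2-fold lower and 1 was at least 2-fold higher, CTGF by 2.62-fold (1.92 to 3.61). After the further month in culture these lists had medians of 0.43, 0.05 and 0.16.

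The matrix gene POSTN stood at 133, 179, 498 and 2249 CPM at weeks 1 to 4, and DLK1 at 95.7, 793, 293 and 902 CPM.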
